A study of Mus musculus with 40 samples.

How the data were processed

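Microarrays with 2 dyes measured RNA of spleen B cells from 20 C57BL/6 mice of 12 weeks, 10 wild-type and 10 Dock10 knockout, in 40 arrays. Per the labels, B cells were isolated by negative selection with magnetic beads, and cells of mice 6 to 10 of each genotype were also cultured for 18 h with or without IL-4 at 10 ng/ml. The arrays are Agilent whole mouse genome arrays, hybridised with a test sample in Cy5 and 1 reference pool, RNA of the knockout cells of mice 6 to 10 before culture, in Cy3. Per the labels, the authors extracted the signals with Agilent Feature Extraction 11.0.1.1 and handled them in GeneSpring GX. The values the authors deposited are log2 ratios of test sample to reference, 1 per probe and array. The log2 unit was checked on the labelling kit's spike-in probes, which lie apart by about the log2 of their fixed ratios. The normalization within arrays, the filters, the annotation and the genome build used are not given in the sources used here.

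The table held 39485 probes, of which 56 were controls. Of the 39429 others, 30625 carried 1 gene symbol and 8804 had none and were not used in the tests per gene. By Entrez identifier 30331 of the named probes matched a RefSeq gene, used only for the names, and 294 did not. Values were averaged over the probes of a gene, of which 6807 genes had several, which gave 21892 genes with 0 missing values. No further normalization or filter was applied. A ratio array has no sequencing depth. Signal intensities were not used here, so the precision is given by the spread between arrays, and the number of arrays limits it. The ratio at the dark corner controls, which hold no target and give the background, ranged from -1.79 to 1.08 between arrays, and that at the first spike-in probe from -0.974 to 1.12.

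The groups were genotype and state: WT_Pre and KO_Pre (n = 10 each), and WT_Ctrl, KO_Ctrl, WT_IL4 and KO_IL4 (n = 5 each). Linear models were fitted per gene with limma 3.58.1 in R 4.3.3, with moderated statistics (eBayes) and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. KO_Pre was compared with WT_Pre in a fit of 20 arrays. The other 8 comparisons came from 1 fit of the 30 arrays of mice 6 to 10, so the groups before culture entered these with n = 5 each. They were genotype without and with IL-4, the IL-4 effect in each genotype and its difference, and the culture effect in each genotype and its difference. The SE is the moderated one.

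Gene lists were written before the data were examined. There were 36, covering B cell functions and subsets, markers of other cell types, stress and signalling responses, metabolism and sex-linked transcripts. The list of immunoglobulin constant regions had 1 measured gene and was not tested, so 35 were tested in each comparison with limma's camera at a preset correlation of 0.01 between genes, and again with a correlation estimated per list. Members were called over all genes, and also with the p adjusted over the list alone. Lists share some genes. The named genes followed a rule set before the data were examined, with clone, predicted and numbered symbols left out. They are the largest log2 differences among called genes in each direction, 10 for KO_Pre vs WT_Pre, WT_IL4 vs WT_Ctrl and WT_Ctrl vs WT_Pre and 5 for the others. Dock10 and Fcer2a were named in every comparison, and the 3 called members with the largest difference in each list.

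Mice carry numbers, and whether equal numbers pair the arrays was checked by correlating residuals. Before culture, arrays of equal number in the 2 genotypes had correlations of 0.225 to 0.543 (mean 0.368, against -0.0338 for unequal numbers). Cells of the same wild-type mouse with and without IL-4 had 0.171 to 0.295, and of the same knockout mouse -0.281 to 0.276. Between genotypes, equal numbers had -0.171 to 0.169 without IL-4 and 0.0911 to 0.299 with it, so these were not treated as pairs.

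Alternatives set before the data were examined were median centring, quantile normalization between arrays, tests per probe, a filter for genes with an SD above the median, eBayes with trend and robust settings, array weights, a 2-fold minimum, all 40 arrays or only the compared groups in a fit, the mouse or mouse number as a block, the mouse as a random block, subsets of the mice before culture, and leaving out each array in turn. Those added after the data were seen were the background ratio and the spike-in ratio as covariates, leaving out wild-type mouse 6, leaving out or replacing the arrays before culture numbered 10, and sex as a block. The pipeline was tested on simulated data with 200 of 21892 genes changed. At a log2 change of 1 it recovered 68% of them for KO_Pre vs WT_Pre, 63% for KO_Ctrl vs WT_Ctrl, 60% for WT_IL4 vs WT_Ctrl and 36% for the difference of the IL-4 effects. At a change of 0.5 it recovered 49%, 15%, 30% and 11%. False calls were 9 of 126, 4 of 82, 9 of 99 and 0 of 47.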

Results

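Gene expression was measured in spleen B cells of 10 wild-type and 10 Dock10 knockout mice, all C57BL/6 and 12 weeks old, on 40 oligonucleotide arrays with 2 dyes. The series asks how the expression profile of B cells without Dock10 differs and how IL-4, a T helper cytokine that acts on B cells, regulates that profile. Cells taken directly after isolation formed the groups WT_Pre and KO_Pre (n = 10 each). Cells of mice 6 to 10 of each genotype were also cultured for 18 h, either with nothing added (WT_Ctrl and KO_Ctrl, n = 5 each) or with IL-4 at 10 ng/ml (WT_IL4 and KO_IL4, n = 5 each). Every sample was hybridised against 1 common reference, a pool of RNA from the KO_Pre cells of mice 6 to 10, so each value is a log2 ratio to knockout B cells before culture. The median log2 ratio of an array lay between -0.33 and -0.005, and its SD between 0.313 and 1.33. All 21892 genes had a value in all 40 arrays, and the number of arrays limits the precision. Xist, the RNA of the inactive X chromosome, had log2 ratios of 4.74 to 5.92 in 10 arrays before culture, those numbered 1 to 4 and 10 of both genotypes. In the same 10 arrays the Y-linked Eif2s3y had log2 ratios of -11.14 to -10.1. The other 30 arrays, which included all 20 cultured samples, had Xist between -1.59 and 0.85 and Eif2s3y between -0.15 and 0.68, so the arrays numbered 10 before and after culture differed in these genes.

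Dock10 mRNA was lower in knockout than in wild-type cells after culture. Its mean log2 ratio without IL-4 was -0.57 ± 0.22 in WT_Ctrl and -1.11 ± 0.33 in KO_Ctrl (SD, n = 5 each). With IL-4 it was 1.59 ± 0.31 in WT_IL4 and 0.52 ± 0.21 in KO_IL4 (SD, n = 5 each). The knockout level thus fell by 0.54 without IL-4 (SE 0.17, adjusted p = 0.0295) and by 1.07 with IL-4 (SE 0.17, adjusted p = 0.000223). Before culture the means were 0.30 ± 0.23 in WT_Pre and -0.08 ± 0.20 in KO_Pre (SD, n = 10 each), and the difference of -0.38 (SE 0.10, adjusted p = 1, unadjusted p = 0.00119) did not pass the test over all genes. Dock10 was lower in the knockout in 9 of 10 pairs of arrays of equal number. This fit did not pair them, although their residuals correlated, and with the number as a block the difference did not pass either (adjusted p = 0.641, unadjusted p = 0.00128). IL-4 raised Dock10 in both genotypes, by 2.16 on the log2 scale in wild-type cells (SE 0.17, adjusted p = 4.97e-10) and by 1.64 in knockout cells (SE 0.17, adjusted p = 1.63e-07). These increases differed between the genotypes by -0.53 (SE 0.24, adjusted p = 0.273), which did not pass. Culture without IL-4 lowered Dock10 in wild-type cells (-0.87, adjusted p = 0.000327) and in knockout cells (-1.02, adjusted p = 1.97e-05), with a difference of -0.16 between them (adjusted p = 0.784).

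The 3 Dock10 probes did not separate the genotypes equally. The 2 probes designed on the reference transcript NM_175291 were lower in the knockout by -0.83 and -0.68 without IL-4 (adjusted p = 0.00159 and 0.0156) and by -1.58 and -1.25 with IL-4 (adjusted p = 4.13e-06 and 0.000139). Before culture the same probes differed by -0.55 and -0.48 (adjusted p = 1 each, unadjusted p = 0.00116 and 0.00154). After culture, the probe designed on the cDNA AK148696 differed by -0.10 and -0.37 (adjusted p = 0.871 and 0.422), so it did not separate them. The common reference cancels in these differences. All 3 probes rose with IL-4 in knockout cells, and they could lie outside the deleted part of the gene. In the comparison without IL-4 the Dock10 call was lost in 8 of 23 alternatives, over which its adjusted p ranged from 0.00159 to 0.472. They included quantile normalization (-0.33) and the spike-in ratio as covariate (-0.50). They also included leaving out array WT_Ctrl 8 (-0.49), WT_Ctrl 9 (-0.49), KO_Ctrl 6 (-0.43) or KO_Ctrl 9 (-0.49).

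**Figure D1:**
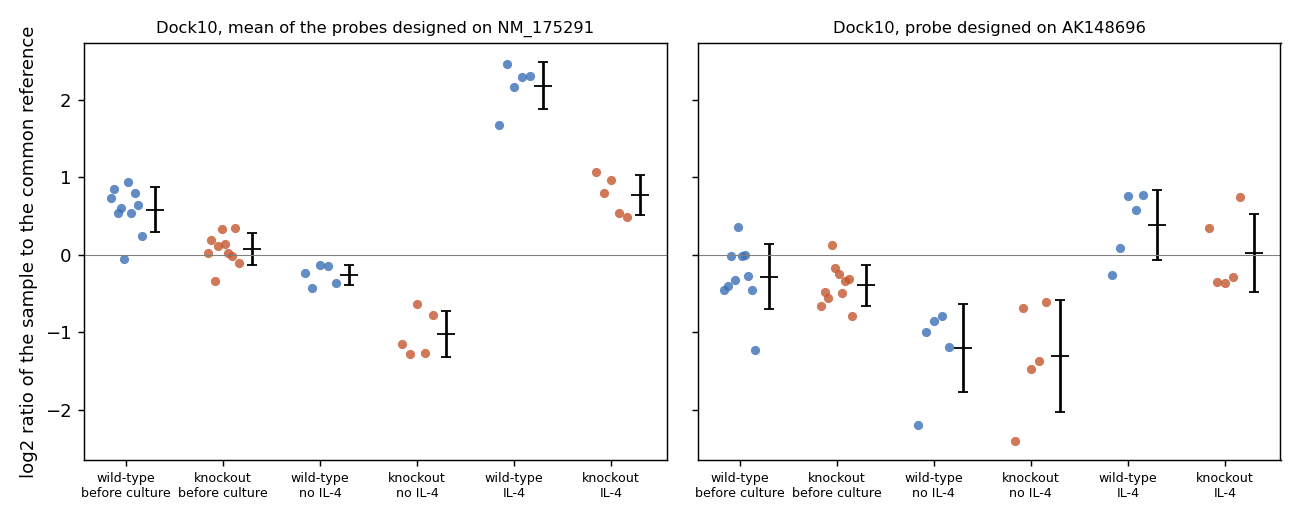
Dock10 log2 ratio to the common reference in each of the 40 arrays (points) by group, with the mean and SD (bars), for the mean of the probes designed on NM_175291 and for the probe designed on AK148696. With IL-4 the wild-type arrays lie above the knockout arrays at the NM_175291 probes, whereas the groups overlap at the AK148696 probe.

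Before culture, markers of other blood cells were lower in the knockout samples as groups, and no single gene passed the test over all genes. The 16 monocyte and macrophage markers had a median log2 difference of -0.60 between KO_Pre and WT_Pre (adjusted p = 3.9e-18; adjusted p = 0.0251 with an estimated correlation). None of them passed over all genes, and 9 were lower when adjusted over the list alone. The mean over arrays of the list's median was 0.48 ± 0.55 in WT_Pre and -0.18 ± 0.46 in KO_Pre (SD, n = 10 each). The 13 dendritic cell markers (-0.20, adjusted p = 3.49e-07; adjusted p = 0.0178 with an estimated correlation) and the 13 markers of B1 cells, an innate-like B cell subset (-0.26, adjusted p = 2.82e-07; adjusted p = 0.0146 with an estimated correlation), were also lower as groups. Genes of glycolysis and glucose uptake shifted little but passed as a group (-0.07, adjusted p = 0.00524; adjusted p = 0.038 with an estimated correlation). The calls of 4 other lists with medians under -0.30 were lost with an estimated correlation. These were the immediate early genes (-0.47, adjusted p = 1.08e-17; adjusted p = 0.0704 with an estimated correlation) and the NK cell markers (-0.54, adjusted p = 2.63e-09; adjusted p = 0.135 with an estimated correlation). The others were the erythroid markers (-0.31, adjusted p = 1.26e-07; adjusted p = 0.102 with an estimated correlation) and the neutrophil markers (-0.73, adjusted p = 6.19e-05; adjusted p = 0.385 with an estimated correlation). The median of the neutrophil markers was 0.78 to 3.26 in the 5 WT_Pre arrays with high Xist (1 to 4 and 10) and 0.07 to 0.17 in the other 5. Among the KO_Pre arrays it was highest in numbers 4 (2.68) and 10 (1.80).

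Gene groups at the centre of B cell function did not pass before culture. The list of B cell receptor signalling (22 genes, median -0.02, adjusted p = 0.368), that of MHC class II antigen presentation (15 genes, median -0.01, adjusted p = 0.958), the actin cytoskeleton list (28 genes, adjusted p = 0.368) and the interferon-stimulated genes (28 genes, median 0.08, adjusted p = 0.0627) were not called. The interferon list was called as higher with sex as a block (adjusted p = 0.0409) and with the background ratio as covariate (0.0154), and not with the mouse number as a block (0.0537), without wild-type mouse 6 (0.598) or with an estimated correlation (0.696). Fcer2a, which encodes the low-affinity IgE receptor CD23, differed by -0.004 (SE 0.18, adjusted p = 1). With limma, 0 of 21892 genes passed, the smallest adjusted p was 1, and 892 genes had an unadjusted p under 0.05 where 1095 would be expected by chance. With the mouse number as a block 0 genes passed and 1620 had an unadjusted p under 0.05. Across genes, the genotype differences of mice 1 to 5 and of mice 6 to 10 had a Pearson correlation of 0.0371 and a Spearman correlation of 0.0762, and genes are not independent replicates. Of the 100 largest differences in mice 1 to 5, 56% had the same sign in mice 6 to 10.

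**Figure D2:**
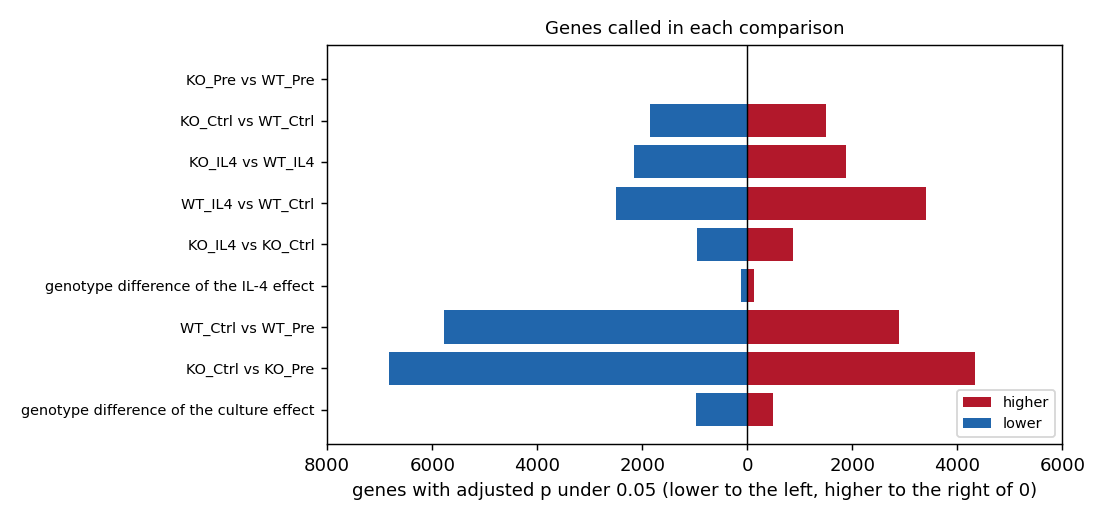
Number of genes with an adjusted p under 0.05 in each of the 9 comparisons, with genes lower in the first-named group left of 0 and higher ones right of 0. No gene passed before culture, 3350 passed between the genotypes after culture without IL-4, and 4032 with IL-4.

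After culture without IL-4, knockout cells had lower interferon-stimulated genes than wild-type cells. Of 28 measured, 25 fell, 0 rose and 3 were not called, with the same counts adjusted over the list alone, and the median log2 difference was -1.50 (adjusted p = 9.52e-26; adjusted p = 0.1 with an estimated correlation). Mx2 fell by 3.12 (SE 0.45, adjusted p = 2.08e-05), Mx1 by 3.06 (SE 0.49, adjusted p = 7.32e-05) and Ifit1 by 2.63 (SE 0.51, adjusted p = 0.000608), all known as interferon-induced genes. Rtp4 (-3.23, SE 0.38, adjusted p = 1.74e-06) and Cmpk2 (-2.99, SE 0.44, adjusted p = 2.2e-05), known as interferon-induced genes too, were also among the 5 largest decreases. The largest was that of Itih5 (-4.02, SE 0.38, adjusted p = 7.43e-08), a member of the inter-alpha-trypsin inhibitor heavy chain family. The median of the interferon list over the 5 arrays of a group was -0.35 ± 0.61 in WT_Ctrl and -1.83 ± 0.13 in KO_Ctrl (mean and SD). In WT_Ctrl it was -1.32 in the array of mouse 6 and between -0.38 and 0.36 in the other 4.

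**Figure D3:**
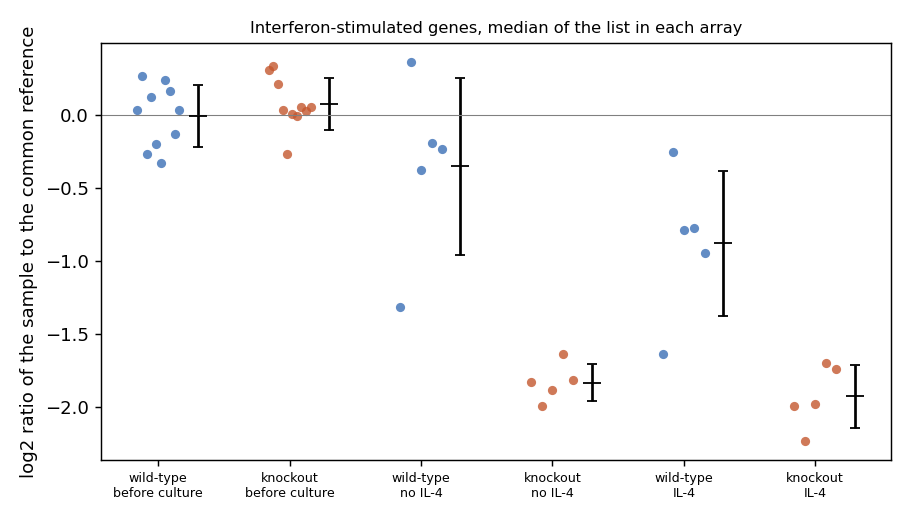
Median log2 ratio of the 28 interferon-stimulated genes in each array (points) by group, with the mean and SD (bars). The 5 KO_Ctrl arrays lie between -2.00 and -1.64, below the 5 WT_Ctrl arrays, which span -1.32 to 0.36.

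Genes of B cell receptor signalling, antigen presentation and the cytoskeleton were lower in KO_Ctrl as well. Of 22 receptor signalling genes 18 fell, also when adjusted over the list alone (median -0.51, adjusted p = 9.22e-12; adjusted p = 0.1 with an estimated correlation), among them the inhibitory receptors Siglecg (-1.31, SE 0.23) and Fcgr2b (-0.95, SE 0.14) and the receptor subunit Cd79b (-0.83, SE 0.13). In the MHC class II list 11 of 15 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone (median -0.61, adjusted p = 3.38e-07; adjusted p = 0.1 with an estimated correlation). Its members include the costimulatory receptor Cd40 (-1.36, SE 0.13, adjusted p = 5.84e-08) and the peptide loading gene H2-DMb2 (-0.97, SE 0.26, adjusted p = 0.00983). Of 28 actin cytoskeleton genes 16 fell, and 20 adjusted over the list alone (median -0.36, adjusted p = 3.42e-11; adjusted p = 0.1 with an estimated correlation), with Vim, an intermediate filament gene, at -1.71 (SE 0.25) and the actin crosslinker Flna at -1.30 (SE 0.15). The MHC class I list had 8 of 15 lower, and 9 adjusted over the list alone (median -0.37, adjusted p = 0.000144; adjusted p = 0.308 with an estimated correlation), including the peptide transporter genes Tap1 (-0.94) and Tap2 (-1.20). Of 8 follicular B cell markers 4 fell, also adjusted over the list alone (median -0.43, adjusted p = 0.0209; adjusted p = 0.133 with an estimated correlation), led by the integrin gene Itgb7 (-2.19, SE 0.20, adjusted p = 5.38e-08). Fcer2a fell by 0.76 (SE 0.25, adjusted p = 0.0381), and this call was lost in 10 of 23 alternatives, over which its adjusted p ranged from 0.00424 to 0.604. They included quantile normalization (-0.38) and leaving out array WT_Ctrl 7 (-0.62), 9 (-0.70) or 10 (-0.74), or KO_Ctrl 6 (-0.65), 7 (-0.69) or 9 (-0.72).

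Genes of ribosome biogenesis and immediate early genes were higher in KO_Ctrl. Of 26 ribosome biogenesis and MYC target genes 14 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone (median 0.38, adjusted p = 5.27e-07; adjusted p = 0.1 with an estimated correlation). The growth regulator Myc itself rose by 0.83 (SE 0.18, adjusted p = 0.00179) and Gnl3 by 0.69 (SE 0.12, adjusted p = 0.000215). Of 23 immediate early genes 7 rose and 1 fell, and 10 rose and 2 fell adjusted over the list alone (median 0.50, adjusted p = 0.00279; adjusted p = 0.564 with an estimated correlation). The transcription factor genes Egr1 and Egr2 rose by 1.91 (SE 0.24) and 1.55 (SE 0.21). The largest increases were those of Serpinb2, a serine protease inhibitor (3.39, SE 0.59, adjusted p = 0.000192), Hpgds, the haematopoietic prostaglandin D synthase (3.17, SE 0.34, adjusted p = 4.38e-07), the chemokine genes Ccl4 (2.86, SE 0.39, adjusted p = 1.05e-05) and Ccl3 (2.83, SE 0.37, adjusted p = 6.12e-06), and Cables1 (2.70, SE 0.45, adjusted p = 0.000107). With quantile normalization the Ccl4 call was lost (2.20), and over its alternatives the adjusted p ranged from 2e-06 to 0.0502.

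Markers of other cells moved between these groups too. T cell markers were lower (15 genes, median -0.60, 3 lower and 1 higher, adjusted p = 0.0411; adjusted p = 0.631 with an estimated correlation). Cd3g had a difference of -2.24 and Cd28 one of 2.03. NK cell markers were higher (12 genes, median 0.32, 2 higher, adjusted p = 0.0327; adjusted p = 0.631 with an estimated correlation). The cytotoxic protease gene Gzmb rose by 1.64, and the call of the list was lost without wild-type mouse 6. Erythroid markers (14 genes, median 0.44, 2 higher, adjusted p = 0.0622; adjusted p = 0.593 with an estimated correlation) and platelet markers (10 genes, median 0.58, 1 higher, adjusted p = 0.0622; adjusted p = 0.564 with an estimated correlation) were not called. Both were called with median centring (adjusted p = 0.044 each), with quantile normalization (0.0324 and 0.000318) and without wild-type mouse 6 (0.0243 and 0.0182). With the mouse number as a block (0.0663 and 0.0471) only the platelet list was, and with the background ratio (0.118 each) or the spike-in ratio (0.0846 and 0.226) as covariate neither. Hbb-b1, a haemoglobin gene given here after its values were seen, was higher by 2.60 (SE 0.44, adjusted p = 0.000141), and in WT_Ctrl it was 2.39 in the array of mouse 6 and between -0.52 and -0.13 in the other 4. Cholesterol biosynthesis genes were lower (19 genes, median -0.23, 5 lower, adjusted p = 0.0276; adjusted p = 0.497 with an estimated correlation). Over all genes limma called 3350 of 21892, of which 1505 rose (44.9%) and 1845 fell. With quantile normalization 19.8% of 660 calls rose. In the fit of only KO_Ctrl and WT_Ctrl 1923 genes passed.

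With IL-4 present, the interferon-stimulated genes were again lower in knockout cells. Of 28 measured, 23 fell and 1 rose in KO_IL4 against WT_IL4, and 25 fell and 1 rose adjusted over the list alone (median -1.21, adjusted p = 1.79e-13; adjusted p = 0.405 with an estimated correlation). Ifit1 fell by 2.74 (SE 0.51, adjusted p = 0.000797), the nucleic acid sensor gene Zbp1 by 1.90 (SE 0.26, adjusted p = 5.76e-05) and Mx2 by 1.87 (SE 0.45, adjusted p = 0.00516). Genes of the unfolded protein response, which expands the folding capacity of the endoplasmic reticulum, were lower in KO_IL4 with 8 of 19, and 11 adjusted over the list alone (median -0.41, adjusted p = 0.00315; adjusted p = 0.329 with an estimated correlation). Among them were the chaperone-related genes Manf (-1.17, SE 0.32) and Sdf2l1 (-0.85, SE 0.13) and the degradation factor Sel1l (-0.89, SE 0.16). Of 15 plasma cell markers 7 fell, also adjusted over the list alone (median -0.52, adjusted p = 0.0126; adjusted p = 0.329 with an estimated correlation). The endoplasmic reticulum degradation gene Derl3 fell by 1.91 (SE 0.21, adjusted p = 4.77e-06) and Prdm1, the regulator of plasma cell differentiation, by 0.74 (SE 0.24, adjusted p = 0.0313). Fcer2a was not called (0.04, SE 0.25, adjusted p = 0.923).

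The same comparison had lower cytoskeleton and antigen presentation genes in KO_IL4. Of 28 actin cytoskeleton genes 12 fell, and 13 adjusted over the list alone (median -0.23, adjusted p = 0.0028; adjusted p = 0.712 with an estimated correlation). Vim had a difference of -1.14 (SE 0.25) and Flna one of -0.89 (SE 0.15). In the MHC class II list 5 of 15 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone (median -0.37, adjusted p = 0.0105; adjusted p = 0.712 with an estimated correlation). Cd40 fell by 1.16 (SE 0.13, adjusted p = 4.77e-06). B cell receptor signalling had 7 of 22 lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone (median -0.24, adjusted p = 0.0398; adjusted p = 0.73 with an estimated correlation). Quantile normalization ended the calls of the actin, MHC class II, receptor signalling and plasma cell lists. Immediate early genes were higher, with 3 of 23 up and 1 down, also adjusted over the list alone (median 0.37, adjusted p = 0.0307; adjusted p = 0.73 with an estimated correlation), and this call was lost without wild-type mouse 6. Cell cycle genes were lower (median -0.31, 3 of 29 lower and 0 adjusted over the list alone, adjusted p = 0.0314; adjusted p = 0.73 with an estimated correlation), a call lost with quantile normalization. The IL-4 and STAT6 response list was not called (8 of 29 lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone, adjusted p = 0.175), nor were the T cell markers (7 of 15 lower and 2 higher, median -0.92, adjusted p = 0.175), of which Cd3g had -2.42 and Cd3d -2.22.

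The largest decreases in KO_IL4 were those of Upb1, an enzyme of pyrimidine breakdown (-2.84, SE 0.33, adjusted p = 5.82e-06), Ifit1, the cystine transporter gene Slc7a11 (-2.69, SE 0.93, adjusted p = 0.0449), the retinol-binding protein gene Rbp7 (-2.67, SE 0.91, adjusted p = 0.0409) and the T cell transcription factor gene Bcl11b (-2.66, SE 0.64, adjusted p = 0.00505). The Slc7a11 call was lost in 11 of 23 alternatives (adjusted p 0.0196 to 0.206), among them the mouse number as a block (adjusted p = 0.0555). Without array KO_IL4 6 its difference was -1.23, and it was also lost without KO_IL4 9 (-2.98) or WT_IL4 6 (-2.43), 8 (-2.60), 9 (-2.68) or 10 (-2.68). That of Rbp7 was lost in 8 alternatives (adjusted p 0.0179 to 0.205), including those without WT_IL4 6, 8, 9 (-2.63) or 10 (-2.64), and its difference was -1.14 without KO_IL4 6. The largest increases were those of Hao1, a glycolate oxidase gene (4.01, SE 0.84, adjusted p = 0.00198), Susd4 (3.39, SE 0.77, adjusted p = 0.00342), Speer4cos (3.17, SE 0.48, adjusted p = 0.000126), Papln (3.14, SE 0.72, adjusted p = 0.00365) and the desmosomal cadherin gene Dsg1c (3.12, SE 0.64, adjusted p = 0.00161). Speer4cos, Papln and Dsg1c belong to a block of 143 genes that varied together between arrays, and the Papln call was lost with quantile normalization (2.70). limma called 4032 genes, of which 1876 rose (46.5%) and 2156 fell, and 2594 without array KO_IL4 9. At 2-fold or more 835 rose and 345 fell. With quantile normalization 60.2% of 1449 calls rose. With the spike-in ratio as covariate 1729 genes passed.

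IL-4 induced feedback regulators of cytokine signalling in wild-type cells. Cish rose by 5.28 (SE 0.52, adjusted p = 2.52e-08) and Socs1 by 4.19 (SE 0.35, adjusted p = 1.14e-09) in WT_IL4 against WT_Ctrl, and the transcription factor gene Nfil3 by 3.89 (SE 0.48, adjusted p = 1.06e-06). The median over all genes was 0.12 higher in WT_IL4 (0.06 with quantile normalization), and changes of lists are therefore also given relative to it. Of 29 genes of the IL-4 and STAT6 response 15 rose and 4 fell, and 17 rose and 4 fell adjusted over the list alone (median 0.81, or 0.68 relative to all genes, adjusted p = 3.29e-05; adjusted p = 0.00923 with an estimated correlation). Genes of the unfolded protein response rose with 15 of 19, also adjusted over the list alone (median 0.73, or 0.61 relative to all genes, adjusted p = 7.84e-07; adjusted p = 0.0132 with an estimated correlation). Xbp1, a transcription factor of that response, rose by 2.24 (SE 0.16, adjusted p = 6.13e-11) and Sdf2l1 by 1.49 (SE 0.13, adjusted p = 3.73e-09). Of 19 cholesterol biosynthesis genes 14 rose, also adjusted over the list alone (median 0.64, or 0.52 relative to all genes, adjusted p = 9.13e-07; adjusted p = 0.0829 with an estimated correlation), among them the pathway enzymes Mvd (1.08, SE 0.12), Lss (1.09, SE 0.27) and Idi1 (1.00, SE 0.13). Ribosome biogenesis and MYC target genes rose with 16 of 26, and 21 adjusted over the list alone (median 0.46, or 0.34 relative to all genes, adjusted p = 7.84e-07; adjusted p = 0.0801 with an estimated correlation). Oxidative phosphorylation genes rose with 12 of 23, and 13 adjusted over the list alone (median 0.21, or 0.09 relative to all genes, adjusted p = 0.00176; adjusted p = 0.255 with an estimated correlation). Of 20 p53 target and apoptosis regulator genes 11 rose and 1 fell, including Phlda3 at 1.31 and Cdkn1a, a cell cycle inhibitor, at 1.05 (list median 0.35, or 0.23 relative to all genes, adjusted p = 0.0433; adjusted p = 0.119 with an estimated correlation).

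IL-4 lowered genes of B cell receptor signalling and interferon-stimulated genes in wild-type cells. Of 22 receptor signalling genes 12 fell and 1 rose, also adjusted over the list alone (median -0.50, or -0.62 relative to all genes, adjusted p = 2.11e-05; adjusted p = 0.341 with an estimated correlation). The complement receptor gene Cr2 fell by 1.91 (SE 0.17, adjusted p = 2.57e-09), and Fcgr2b fell by 0.93. Of 28 interferon-stimulated genes 11 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone (median -0.52, or -0.64 relative to all genes, adjusted p = 0.000456; adjusted p = 0.578 with an estimated correlation). Ifit3 fell by 1.70, and the guanylate-binding protein gene Gbp5 fell by 1.68. Markers of follicular B cells (4 of 8 lower, median -0.75 relative to all genes, adjusted p = 0.00607; adjusted p = 0.0874 with an estimated correlation) and of marginal zone B cells (4 of 14 lower and 2 higher, median -0.43 relative to all genes, adjusted p = 0.00607; adjusted p = 0.111 with an estimated correlation) fell as groups. Itgb7 (-1.78) and Cd1d1, which encodes a lipid-presenting molecule (-2.00, SE 0.12, adjusted p = 6.36e-12), led these lists. The list of chemokine and trafficking receptors had 7 of 19 lower and 3 higher (median -0.37 relative to all genes, adjusted p = 0.0412; adjusted p = 0.152 with an estimated correlation). Its members include the chemokine receptor genes Ccr6 (-2.00) and Ccr7 (-1.43), and its call was lost with quantile normalization. The MHC class II list was not called (6 of 15 higher and 2 lower, adjusted p = 0.0911), although its members H2-DMa (1.53, SE 0.16) and Cd86 (1.23, SE 0.14) rose. NK cell markers were higher (5 of 12 higher and 1 lower, median 0.54 relative to all genes, adjusted p = 0.0393; adjusted p = 0.578 with an estimated correlation) and neutrophil markers lower (3 of 17 lower, median -0.53 relative to all genes, adjusted p = 0.0412; adjusted p = 0.578 with an estimated correlation). The NK cell call was lost without wild-type mouse 6 (adjusted p = 0.12). The neutrophil call was lost with quantile normalization (adjusted p = 0.105) and with the spike-in ratio (adjusted p = 0.136) or the background ratio (median 0.07, adjusted p = 0.787) as covariate. Fcer2a was not called (-0.004, SE 0.25, adjusted p = 0.991).

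The largest increase with IL-4 in wild-type cells was that of Sertad4 (6.54, SE 0.49, adjusted p = 2.29e-10). Others among the 10 largest were Cst7, which encodes the protease inhibitor cystatin F (4.98, SE 0.45, adjusted p = 4.62e-09), the cytokine receptor gene Lifr (4.71, SE 0.38, adjusted p = 9.29e-10), Tafa3 (4.57), the cytotoxic protease gene Gzmb (4.25, SE 0.37, adjusted p = 2.28e-09), Saxo2 (4.06) and Ffar2, a receptor for short-chain fatty acids (3.92). The largest decreases were those of Anxa1, an annexin (-3.65, SE 0.17, adjusted p = 9.99e-14), and Klrb1, a lectin-like receptor gene (-3.27, SE 0.28, adjusted p = 2.34e-09). The other 8 of the 10 largest decreases, Dsg1c (-3.35), Vmn1r197 (-3.25), Dnajb8 (-3.25), Slc26a1 (-3.23), Papln (-3.21), Stfa2 (-3.17), Trim43b (-3.16) and Speer4cos (-3.15), all belong to the block of 143 genes that follow Papln over the cultured arrays. The block was chosen with this group difference included, so such membership is no separate result. limma called 5899 genes, of which 3394 rose (57.5%) and 2505 fell. Of 1390 that changed at least 2-fold, 509 rose and 881 fell. With quantile normalization 42.9% of 3685 calls rose.

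In knockout cells IL-4 raised cholesterol biosynthesis and IL-4 response genes. Of 19 cholesterol biosynthesis genes 14 rose in KO_IL4 against KO_Ctrl, and 16 adjusted over the list alone (median 0.85, adjusted p = 6.72e-21; adjusted p = 0.00107 with an estimated correlation). Lss rose by 1.24 (SE 0.27) and Idi1 by 1.18 (SE 0.13, adjusted p = 4.58e-07). Of 29 genes of the IL-4 and STAT6 response 11 rose and 1 fell, and 12 rose and 3 fell adjusted over the list alone (median 0.33, adjusted p = 0.000489; adjusted p = 0.0144 with an estimated correlation). Cish rose by 3.60 (SE 0.52, adjusted p = 2.89e-05), Socs1 by 3.00 (SE 0.35, adjusted p = 8.62e-07) and Nfil3 by 2.56 (SE 0.48, adjusted p = 0.000801). The MHC class II list had 8 of 15 higher, and 9 higher and 1 lower adjusted over the list alone (median 0.61, adjusted p = 1.05e-06; adjusted p = 0.133 with an estimated correlation). The peptide loading genes H2-DMa and H2-DMb2 rose by 1.68 (SE 0.16) and 1.71 (SE 0.26). The unfolded protein response list had 4 of 19 higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone (median 0.22, adjusted p = 0.0138; adjusted p = 0.193 with an estimated correlation). Xbp1 rose by 1.65 (SE 0.16, adjusted p = 4.03e-08). Interferon-stimulated genes were not called (3 of 28 lower, adjusted p = 0.258). Fcer2a rose by 0.80 (SE 0.25, adjusted p = 0.0451) but was called in only 8 of 23 alternatives (adjusted p 0.0102 to 0.537). It was lost with the mouse as a fixed block (adjusted p = 0.0547), though not as a random block, and without array KO_Ctrl 6 (0.69), 7 (0.73), 9 (0.76) or 10 (0.86), among others.

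Markers of some B cell subsets fell with IL-4 in knockout cells, while follicular markers did not (1 of 8 higher and 2 lower, median 0.005, adjusted p = 0.292). Marginal zone markers had 3 of 14 lower and 1 higher, and 7 lower and 1 higher adjusted over the list alone (median -0.38, adjusted p = 0.00745; adjusted p = 0.133 with an estimated correlation). Cd1d1 fell by 1.24. B1 cell markers fell as well (4 of 13 lower and 1 higher, median -0.39, adjusted p = 0.0174; adjusted p = 0.133 with an estimated correlation). Plasma cell markers had 4 of 15 lower and 1 higher (median -0.07, adjusted p = 0.0499; adjusted p = 0.193 with an estimated correlation). Sdc1, the plasma cell surface proteoglycan CD138, fell by 2.91 (SE 0.24, adjusted p = 3.88e-09). Erythroid markers were lower (3 of 14 lower, median -0.68, adjusted p = 0.00641; adjusted p = 0.292 with an estimated correlation). So were platelet markers (1 of 10 lower, median -0.96, adjusted p = 0.002; adjusted p = 0.193 with an estimated correlation) and monocyte markers (2 of 16 lower and 1 higher, median -0.34, adjusted p = 0.0174; adjusted p = 0.265 with an estimated correlation). Sertad4 (3.91, SE 0.49, adjusted p = 3.18e-06), Cst7 (3.67, SE 0.45, adjusted p = 2.05e-06) and Hao1 (3.21, SE 0.84, adjusted p = 0.0158) were among the largest increases. The Hao1 call was lost in 4 of 23 alternatives (adjusted p 1.79e-06 to 0.188), including those without array KO_Ctrl 7 (2.64) or KO_Ctrl 9 (2.77). The largest decreases were those of the inflammatory cytokine gene Il1b (-3.29, SE 0.57, adjusted p = 0.000339), the matrix protein gene Thbs1 (-3.06, SE 0.65, adjusted p = 0.00286), Slc7a11 (-3.001, SE 0.93, adjusted p = 0.0439), Serpinb2 (-2.93, SE 0.59, adjusted p = 0.00165) and Sdc1. The Il1b call was lost with quantile normalization (-2.62), and those of Thbs1 and Serpinb2 when only the compared groups were fitted. The Slc7a11 call was lost in 10 of 23 alternatives (adjusted p 0.0179 to 0.268), among them the mouse as a block (adjusted p = 0.0551). These included leaving out KO_IL4 6 (-1.54) or 8 (-3.26), or KO_Ctrl 6 (-2.94), 7 (-2.95), 9 (-2.89) or 10 (-2.79). limma called 1838 genes, of which 876 rose and 962 fell, 1211 without array KO_IL4 7, and 350 with quantile normalization.

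The IL-4 responses of the genotypes differed in genes of the unfolded protein response, with a smaller increase in knockout cells. Of 19 measured, 3 had a lower IL-4 effect in the knockout, and 10 adjusted over the list alone (median -0.51, adjusted p = 5.27e-06; adjusted p = 0.066 with an estimated correlation). They were Sel1l (-1.02, SE 0.23, adjusted p = 0.0276), Sdf2l1 (-0.86, SE 0.19, adjusted p = 0.0235) and Herpud1 (-0.63, SE 0.14, adjusted p = 0.0235), all with roles in folding or degradation at the endoplasmic reticulum. Ribosome biogenesis and MYC target genes had 2 of 26 with a lower effect, and 8 adjusted over the list alone (median -0.35, adjusted p = 3.21e-06; adjusted p = 0.139 with an estimated correlation). Of the IL-4 and STAT6 response 1 of 29 had a lower effect, and 6 adjusted over the list alone (median -0.60, adjusted p = 0.0139; adjusted p = 0.139 with an estimated correlation). That gene was Vdr, the vitamin D receptor (-2.20, SE 0.48, adjusted p = 0.0235). Cish did not pass (-1.68, adjusted p = 0.254). Its mean was 0.68 ± 0.23 in WT_Ctrl and 2.54 ± 2.00 in KO_Ctrl, but 5.964 in WT_IL4 and 6.135 in KO_IL4 (SD, n = 5 each). For ribosome biogenesis genes the genotypes differed without IL-4 (median 0.38) and not with it (-0.006), so the lower effect went with the untreated level. Between the genotypes the IL-4 response list had medians of 0.105 without and -0.308 with IL-4, neither called. The plasma cell regulator Prdm1 (-1.47, SE 0.34, adjusted p = 0.0297) and Derl3 (-1.45, SE 0.30, adjusted p = 0.0147) also had a lower effect. Receptor signalling genes had a higher effect as a group (1 of 22 called, also adjusted over the list alone, median 0.29, adjusted p = 5.27e-06; adjusted p = 0.497 with an estimated correlation). The gene called was Cr2 (1.19, SE 0.23, adjusted p = 0.0126). Follicular B cell markers had a higher effect with no single gene called (0 of 8, and 1 adjusted over the list alone, median 0.40, adjusted p = 0.0133; adjusted p = 0.152 with an estimated correlation). Interferon-stimulated genes had a higher effect too (1 of 28, also adjusted over the list alone, median 0.43, adjusted p = 0.00153; adjusted p = 0.686 with an estimated correlation). Among them Gbp5 was called (1.20, SE 0.29, adjusted p = 0.0366). In these lists a higher effect was a smaller decrease with IL-4, or none. The median change of receptor signalling genes was -0.50 in wild-type and -0.11 in knockout cells. That of follicular markers was -0.63 and 0.005, and that of interferon-stimulated genes -0.52 and -0.09. Cholesterol biosynthesis genes had a slightly higher effect with no single gene called (0 of 19, median 0.15, adjusted p = 0.00744; adjusted p = 0.522 with an estimated correlation). So had those of MHC class II presentation (0 of 15, median 0.27, adjusted p = 0.0235; adjusted p = 0.548 with an estimated correlation). NK cell markers had a lower effect (1 of 12, median -0.65, adjusted p = 0.00744; adjusted p = 0.551 with an estimated correlation).

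**Figure D4:**
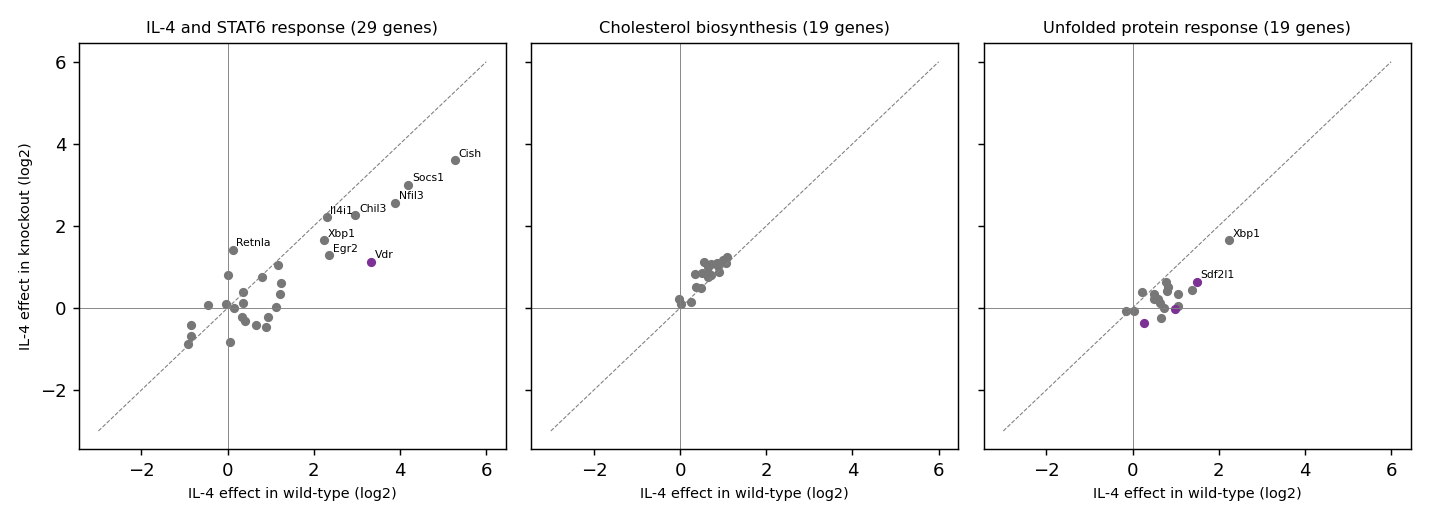
IL-4 effect (log2) in wild-type and in knockout cells for each measured gene of the IL-4 and STAT6 response, cholesterol biosynthesis and unfolded protein response lists, with the line of equality dashed and the genes whose effects differed between genotypes in purple. Most unfolded protein response genes lie below the line.

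Among single genes, Gzmb had the lowest IL-4 effect in the knockout relative to the wild-type (-3.64, SE 0.52, adjusted p = 0.000565), followed by Serpinb2 (-3.48, SE 0.84, adjusted p = 0.0383), which fell with IL-4 in knockout cells (-2.93) and was not called in wild-type cells (0.55, adjusted p = 0.514), the collagenase gene Mmp13 (-2.98, SE 0.54, adjusted p = 0.00726), Ffar2 (-2.78, SE 0.61, adjusted p = 0.0259) and the cadherin gene Cdh1 (-2.60, SE 0.46, adjusted p = 0.00522). A higher effect was found for Hao1 (5.37, SE 1.19, adjusted p = 0.0265), Ssty1 (3.70, SE 0.81, adjusted p = 0.0235), the signalling scaffold gene Cnksr1 (3.70, SE 0.70, adjusted p = 0.00866), Speer4cos (3.35, SE 0.67, adjusted p = 0.0137) and the noncoding RNA gene Ipw (3.25, SE 0.62, adjusted p = 0.0087). Speer4cos and Ipw belong to the block of genes that follow Papln. limma called 261 genes, of which 133 had a higher and 128 a lower effect in the knockout, 353 with the mouse as a fixed block and 467 with it as a random block. The share that was higher was 51%, and 84% with quantile normalization. The count changed with single arrays. It was 503, 138, 168, 128 and 151 without WT_Ctrl 6, 7, 8, 9 and 10, and 127 and 159 without WT_IL4 8 and 10. It was 109, 1309 and 120 without KO_Ctrl 7, 8 and 9, and 172, 97 and 151 without KO_IL4 6, 9 and 10. Without KO_Ctrl 7 the calls of Ffar2 (-2.54), Hao1 (4.80), Ssty1 (3.36) and Serpinb2 (-2.78) were lost. Those of Hao1 and Ssty1 were also lost without KO_Ctrl 9 (4.93 and 3.33) or KO_IL4 9 (5.26 and 3.48), and that of Hao1 without WT_Ctrl 7 (5.09). The Serpinb2 call was lost in 12 of 32 alternatives (adjusted p 0.00819 to 0.0831), including those without WT_Ctrl 7, 8 or 9, WT_IL4 7, 8 or 9, KO_Ctrl 6, or KO_IL4 6, 9 or 10. Across genes the IL-4 effects of the genotypes had a Pearson correlation of 0.427 and a Spearman correlation of 0.413, and genes are not independent replicates. Of the genes called in knockout cells, 671 of the higher ones (76.6%) and 622 of the lower ones (64.7%) were called in the same direction in wild-type cells, where 136 and 110 would be expected by chance, and 17 were called in opposite directions.

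Culture for 18 h without IL-4 lowered immediate early genes and cell cycle genes in wild-type cells. Of 23 immediate early genes 21 fell in WT_Ctrl against WT_Pre of mice 6 to 10 (n = 5 each), also adjusted over the list alone (median -2.43, or -2.28 relative to all genes, adjusted p = 1.03e-15; adjusted p = 0.097 with an estimated correlation), led by the transcription factor gene Fos (-7.63, SE 0.27, adjusted p = 7.87e-17). The median over all genes was -0.15 (-0.02 with median centring), and changes of lists are therefore also given relative to it. Of 29 cell cycle genes 25 fell and 1 rose, and 26 fell and 1 rose adjusted over the list alone (median -0.60 relative to all genes, adjusted p = 1.52e-07; adjusted p = 0.188 with an estimated correlation). The checkpoint kinase gene Bub1 fell by 3.08. Heat shock genes fell with 10 of 13, and 1 rose (median -0.87 relative to all genes, adjusted p = 0.000323; adjusted p = 0.188 with an estimated correlation). The growth regulator Myc fell by 2.61 (SE 0.18). MHC class II genes (10 of 15 lower, median -0.47 relative to all genes, adjusted p = 0.00253; adjusted p = 0.275 with an estimated correlation) and marginal zone markers (6 of 14 lower and 1 higher, median -0.43 relative to all genes, adjusted p = 0.00429; adjusted p = 0.133 with an estimated correlation) fell as well.

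Genes of amino acid transport and cholesterol biosynthesis rose with culture in wild-type cells. Amino acid transporters had 5 of 12 higher and 2 lower, and 6 higher and 2 lower adjusted over the list alone (median 0.44, or 0.59 relative to all genes, adjusted p = 0.00108; adjusted p = 0.133 with an estimated correlation). Slc7a11 rose by 2.69 and the glycine transporter gene Slc6a9 by 2.25. Trib3 (5.00, SE 0.19, adjusted p = 1.56e-16), the asparagine synthetase gene Asns (3.94, SE 0.22, adjusted p = 4.3e-13) and Chac1 (3.83, SE 0.44), all known targets of the stress factor ATF4, rose, while the unfolded protein response list, which holds all 3, was not called (4 of 19 higher and 10 lower, adjusted p = 0.362). Of 19 cholesterol biosynthesis genes 8 rose and 1 fell, also adjusted over the list alone (median 0.38 relative to all genes, adjusted p = 1.89e-05; adjusted p = 0.141 with an estimated correlation), among them Sqle and Msmo1. Other large increases were those of the ribonuclease gene Rnase10 (5.98, SE 0.61, adjusted p = 4.1e-08), the cytokine gene Il6 (4.85, SE 0.57, adjusted p = 4.01e-07), the xenobiotic enzyme gene Cyp1a1 (4.20, SE 0.39, adjusted p = 9.84e-09) and the homeobox gene Dlx5 (4.56). Fcer2a was not called (-0.21, SE 0.25, adjusted p = 0.521).

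Markers of some other cell types fell with culture in wild-type cells. Dendritic cell markers had 8 of 13 lower, also adjusted over the list alone (median -1.34, or -1.19 relative to all genes, adjusted p = 0.000133; adjusted p = 0.00484 with an estimated correlation). The receptor genes Clec9a (-4.94, SE 0.27, adjusted p = 2.88e-13) and Xcr1 (-3.64) fell most. NK cell markers had 11 of 12 lower (median -2.11 relative to all genes, adjusted p = 5.98e-06; adjusted p = 0.188 with an estimated correlation). By the same measures, platelet markers had 7 of 10 lower (-1.34, adjusted p = 0.0134; 0.301). Monocyte and macrophage markers had 8 of 16 lower and 3 higher (-0.67, adjusted p = 0.0489; 0.351). T cell, neutrophil, erythroid and stromal markers were not called (adjusted p = 0.922, 0.913, 0.195 and 0.811). Large decreases were those of the macrophage genes Mrc1 (-4.28, SE 0.50, adjusted p = 3.35e-07), Itgad (-4.55) and Adgre4 (-4.50) and of the matrix gene Fn1 (-4.37). limma called 8654 genes, of which 2879 rose (33.3%, 50.5% with median centring and 54.3% with quantile normalization) and 5775 fell. With the background ratio as covariate 4614 genes passed.

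Culture lowered interferon-stimulated genes in knockout cells. Of 28 measured, 26 fell in KO_Ctrl against KO_Pre of mice 6 to 10 (n = 5 each), and 27 adjusted over the list alone (median -1.78, or -1.66 relative to all genes, adjusted p = 1.22e-10; adjusted p = 0.2 with an estimated correlation). Mx1 (-3.73, SE 0.49), Mx2 (-3.68, SE 0.45) and Ifit1 (-3.60, SE 0.51) were among them. In wild-type cells this list was not called (6 of 28 lower and 1 higher, adjusted p = 0.481). The median over all genes was -0.12 in knockout cells (-0.02 with median centring). Genes of receptor signalling fell (18 of 22 lower, median -0.64 relative to all genes, adjusted p = 1.13e-06; adjusted p = 0.2 with an estimated correlation). The actin cytoskeleton list had 23 of 28 lower and 1 higher (median -0.50 relative to all genes, adjusted p = 1.02e-07; adjusted p = 0.18 with an estimated correlation). The MHC class II list had 12 of 15 lower and 2 higher (median -1.18 relative to all genes, adjusted p = 2.61e-05; adjusted p = 0.18 with an estimated correlation). The MHC class I list had 12 of 15 lower (median -0.66 relative to all genes, adjusted p = 7.43e-05; adjusted p = 0.2 with an estimated correlation). Examples were Cd40 (-2.32, SE 0.13, adjusted p = 1.38e-13), Vim (-2.59, SE 0.25) and Siglecg (-1.62). Immediate early genes fell with 19 of 23, and 1 rose (median -1.14 relative to all genes, adjusted p = 1.94e-05; adjusted p = 0.252 with an estimated correlation), led by Fos (-6.09, SE 0.27, adjusted p = 2.9e-15). Cell cycle genes fell with 20 of 29, and 1 rose (median -0.54 relative to all genes, adjusted p = 0.000281; adjusted p = 0.364 with an estimated correlation). Fcer2a fell by 1.09 (SE 0.25, adjusted p = 0.000726), a call lost with quantile normalization (-0.39) and with the background ratio as covariate (-0.35).

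Genes of amino acid transport rose with culture in knockout cells too. Of 12 amino acid transporters 8 rose and 3 fell (median 1.15, or 1.27 relative to all genes, adjusted p = 0.00183; adjusted p = 0.18 with an estimated correlation), and Trib3 (5.93, SE 0.19, adjusted p = 3.9e-18), Asns (5.08) and Chac1 (5.02) rose. The unfolded protein response list, which holds these 3, was not called (7 of 19 higher and 11 lower, median -0.55, or -0.43 relative to all genes, adjusted p = 0.815). Other large increases were those of Rnase10 (7.06, SE 0.61), Il6 (6.38, SE 0.57, adjusted p = 1.34e-09), Ctxn2 (5.40) and Gabrp (5.29), and large decreases those of Itih5 (-5.10, SE 0.38), Abcg3 (-4.87), Mycl (-4.61) and Mrc1 (-4.53, SE 0.50, adjusted p = 4.23e-08). B1 cell markers rose as a group (8 of 13 higher and 2 lower, median 0.74 relative to all genes, adjusted p = 0.0369; adjusted p = 0.18 with an estimated correlation). Dendritic cell markers (8 of 13 lower and 1 higher, median -0.79 relative to all genes, adjusted p = 0.0371; adjusted p = 0.18 with an estimated correlation) and NK cell markers (9 of 12 lower and 1 higher, median -1.04 relative to all genes, adjusted p = 0.0369; adjusted p = 0.573 with an estimated correlation) fell. limma called 11155 genes, of which 4330 rose (38.8%, and 50.4% with quantile normalization) and 6825 fell. With the background ratio as covariate 5477 genes passed.

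The effect of culture differed between the genotypes in interferon-stimulated genes. Of 28 measured, 22 had a lower culture effect in the knockout, and 23 adjusted over the list alone (median -1.56, adjusted p = 3.39e-23; adjusted p = 0.1 with an estimated correlation). Mx1 had -3.22 (SE 0.70, adjusted p = 0.00413), and the interferon-induced gene Cmpk2 had -3.20 (SE 0.62, adjusted p = 0.00157). Itih5 (-4.22, SE 0.54, adjusted p = 3.3e-05), Rtp4 (-3.31, SE 0.54, adjusted p = 0.000355) and Ifit1bl1 (-3.26, SE 0.61) were the other large decreases. Receptor signalling genes also had lower effects (9 of 22, and 16 adjusted over the list alone, median -0.54, adjusted p = 1.84e-10; adjusted p = 0.1 with an estimated correlation). Those of the actin cytoskeleton did too (7 of 28, and 15 adjusted over the list alone, median -0.42, adjusted p = 1.84e-10; adjusted p = 0.1 with an estimated correlation). The same held for MHC class II (5 of 15 lower and 1 higher, and 11 lower and 1 higher adjusted over the list alone, median -0.63, adjusted p = 1.69e-06; adjusted p = 0.1 with an estimated correlation). Cd40 had -1.59 (SE 0.18, adjusted p = 1.33e-05), Vim -1.74 and Siglecg -1.28. MHC class I genes had lower effects as a group (3 of 15, and 5 adjusted over the list alone, median -0.44, adjusted p = 0.000337; adjusted p = 0.235 with an estimated correlation). Fcer2a did not pass (-0.88, adjusted p = 0.152).

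In the knockout, ribosome biogenesis genes had a higher culture effect, and immediate early genes fell less. Of 26 ribosome biogenesis and MYC target genes 12 were higher, and 15 adjusted over the list alone (median 0.50, adjusted p = 7.64e-10; adjusted p = 0.0633 with an estimated correlation). Myc itself had 1.23 (SE 0.26). Of 23 immediate early genes 5 were higher, and 14 higher and 1 lower adjusted over the list alone (median 1.14, adjusted p = 3.81e-07; adjusted p = 0.196 with an estimated correlation). Egr1 had 2.13 and Fos 1.54. The largest single differences were those of Hpgds (3.49, SE 0.48, adjusted p = 7.32e-05), Cables1 (3.29, SE 0.64, adjusted p = 0.00157), the T cell costimulatory receptor gene Cd28 (3.15, SE 0.53, adjusted p = 0.000447), Serpinb2 (3.14, SE 0.84, adjusted p = 0.0209) and the haemoglobin gene Hbb-b1 (3.06, SE 0.62, adjusted p = 0.00264). With quantile normalization the Serpinb2 call was lost (2.63). Markers of other cells had a higher effect too. They were those of erythroid cells (4 of 14, and 6 adjusted over the list alone, median 1.19, adjusted p = 5.75e-05; adjusted p = 0.14 with an estimated correlation) and of monocytes and macrophages (2 of 16, and 9 adjusted over the list alone, median 0.92, adjusted p = 7.67e-05; adjusted p = 0.1 with an estimated correlation). NK cell markers (1 of 12, median 0.80, adjusted p = 0.00141; adjusted p = 0.382 with an estimated correlation) and platelet markers (0 of 10, median 0.72, adjusted p = 0.036; adjusted p = 0.382 with an estimated correlation) were higher too. The NK cell markers fell with culture in both genotypes, and less in the knockout. limma called 1462 genes, of which 485 were higher (33.2%) and 977 lower. With quantile normalization 19.5% of 359 calls were higher. With array weights 3387 genes passed.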

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

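The tests of a mislabelled sample and of a mixture for wild-type mouse 6, of RNA as labelled for the arrays numbered 10 and of a shared signal of the Papln block were chosen after the result was seen, as were the alternatives that leave out mouse 6 or use a covariate. Single arrays far from the others of their group are listed next. Of 301 groups of values examined 30 held such an array, where chance alone gives about 1 in 20, or 15.

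The IL-4 targets Cish and Socs1 had single wild-type arrays apart from the rest. In WT_Ctrl, mouse 6 had Cish at 1.1 and Socs1 at -1.38, and in WT_IL4 it had Socs1 at 3.04. Its Dock10 in WT_IL4 was 1.04, its unfolded protein response median there 0.023, and its spike-in ratio there -0.162. In WT_Ctrl it also had Mrc1 at -4.51, Hbb-b1 at 2.39, Dsg1c at 3.36 and Stfa2 at 3.42. The WT_IL4 array of mouse 7 had Cst7 at 4.70, Rbp7 at -0.53 and a neutrophil marker median of -0.705. In KO_IL4, mouse 6 had Slc7a11 at -6.64 and Rbp7 at -7.67, mouse 10 had medians of -1.04 for MHC class II and -1.15 for B cell receptor signalling, and mouse 7 a median of -1.47 for immediate early genes. In KO_Ctrl, mouse 8 had Slc7a11 at 0.487 and a cholesterol biosynthesis median of -0.0625, mouse 7 had Cdh1 at 0.305, and mouse 10 had Fos at -5.64 and an IL-4 response median of 0.407. Before culture, KO_Pre 5 had Rnase10 at 2.20, Trib3 at 1.23, Ctxn2 at 1.37 and Rtp4 at -0.964. WT_Pre 10 had Olfr661 at -2.81, WT_Pre 2 had Dlx5 at 1.57, and WT_Pre 5 a ribosome biogenesis median of -0.278.

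By a test of the difference itself, the effect of IL-4 differed between the genotypes in 261 genes and that of culture in 1462. The 5 largest named genes in each direction for IL-4 were Hao1 (5.37), Ssty1 (3.70), Cnksr1 (3.70), Speer4cos (3.35), Ipw (3.25), Gzmb (-3.64), Serpinb2 (-3.48), Mmp13 (-2.98), Ffar2 (-2.78) and Cdh1 (-2.60). For culture those 10 were Hpgds (3.49), Cables1 (3.29), Cd28 (3.15), Serpinb2 (3.14), Hbb-b1 (3.06), Itih5 (-4.22), Rtp4 (-3.31), Ifit1bl1 (-3.26), Mx1 (-3.22) and Cmpk2 (-3.20).

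The cultured arrays of wild-type mouse 6 lay between the genotypes. On a scale from the other wild-type arrays (0) to the knockout (1) over the 500 genes that best separate them, it stood at 0.586 without and 0.472 with IL-4, while the other 4 stood between -0.112 and 0.13. For the array with IL-4, cells of a knockout mouse under a wrong label are argued against by Dock10, which exceeded the highest knockout array by 0.61 as the mean of the 2 probes that separate the genotypes (knockout SD 0.254), and by 0.209 as the mean of all 3 probes (SD 0.21). A mixture with knockout RNA may explain that array (Dock10 position 0.409 with 2 and 0.572 with 3 probes), whereas for the array without IL-4 neither can be told apart, since with 2 probes its Dock10 lay above the knockout arrays by 0.39 (position -0.037) and with 3 probes inside their range (-0.89, against -1.56 to -0.721; position 0.635). A culture or array batch shared with the knockout stays open as a hypothesis, since the spike-in ratio of mouse 6 lay inside the knockout range and outside that of the other wild-type arrays in 2 of 2 treatments (0.403 and -0.162), and no biological explanation was tested.

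Without wild-type mouse 6 the interferon-stimulated genes had a median difference between the genotypes of -1.71 without and -1.34 with IL-4.

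The arrays before culture numbered 10 had Xist and no Y-linked signal in both genotypes, unlike the cultured arrays numbered 10. RNA of the labelled mouse that was also part of the reference pool is argued against, since a pool with 1 part in 5 of such RNA allows a log2 ratio of at most 2.32 and KO_Pre 10 had 4.99. An exchange of the labels 5 and 10 before culture cannot be told apart from other causes. In 1 of 4 sets of cultured arrays number 10 correlated more with the array labelled 5, and the correlations were small (-0.141 to 0.108). With the arrays numbered 5 in place of 10, 8142 genes were called for culture in wild-type and 10941 in knockout cells.

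A block of 143 genes that follow Papln (correlation above 0.9 over the 20 cultured arrays), 27 of them with clone or predicted symbols and 6 olfactory or vomeronasal receptors, was lower with IL-4 in wild-type cells, by a median of -1.89. The amount of spike-in RNA and the background of the arrays are each argued against as the whole cause, because the median difference was -1.53 and -1.78 with them as covariates. These genes may share a signal that varies between arrays of 1 group, a hypothesis, since their mean pairwise correlation within groups before culture was 0.321, against 0.013 to 0.085 in 100 random sets. Within groups the block correlated with the spike-in ratio over 40 arrays (Pearson 0.425, permutation p = 0.0118; Spearman 0.435; Pearson 0.587 without the 2 farthest arrays). No biological explanation was tested.

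For other splits of the same arrays into groups of equal size, chance can be excluded for 4 counts, where 1 split of 100, the real one, gave as many genes. The 4 counts were KO_Ctrl vs WT_Ctrl (3350, highest other 2294), KO_IL4 vs WT_IL4 (4032, highest other 1816), the genotype difference of the IL-4 effect (261, highest other 95) and that of the culture effect (1462, highest other 1). The highest other splits of the first 3 put wild-type mouse 6 with the knockout arrays. For KO_Pre vs WT_Pre the real count was 0, which all 100 splits reach by construction, so this test says nothing about chance. Its splits that part the equal numbers gave at most 1 gene, and splits of any other kind up to 904, which points to a structure of the samples. For the effects of IL-4 and culture within a genotype, the splits that part the mice number 16, too few to call chance unlikely. The counts were 5899 (highest other 15), 1838 (432), 8654 (4773) and 11155 (4980), and the highest other of the last 2 had number 10 exchanged. Splits of any other kind reached 1014, 978, 3893 and 7948.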

How the results depend on the processing

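The covariates, fits without wild-type mouse 6, other arrays for those numbered 10 and sex as a block were chosen after the data were seen. The interferon-stimulated genes were lower in the knockout after culture under every scaling tried, with medians of -1.15 without IL-4 and -0.79 with IL-4 under quantile normalization. The lists of the unfolded protein response and of cholesterol biosynthesis rose with IL-4 in wild-type cells under the same settings. KO_Pre vs WT_Pre gave 0 genes under every alternative, including those without 1 array.

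Quantile normalization gave 660 genes for KO_Ctrl vs WT_Ctrl, 1449 for KO_IL4 vs WT_IL4, 3685 for WT_IL4 vs WT_Ctrl, 350 for KO_IL4 vs KO_Ctrl and 359 for the genotype difference of the culture effect, and kept 19.6%, 34.8%, 60.4%, 19% and 22.8% of the genes called before. The cause was not tested. Keeping only genes with an SD above the median gave 1184, 2116, 2324, 821, 159, 5242, 6137 and 518 genes (KO_Ctrl vs WT_Ctrl, KO_IL4 vs WT_IL4, WT_IL4 vs WT_Ctrl, KO_IL4 vs KO_Ctrl, the difference of the IL-4 effects, culture in wild-type, culture in knockout, and the difference of the culture effects), since fewer genes were tested. A minimum of 2-fold gave 634, 1180, 1390, 499, 169, 2966, 4484 and 536 by its construction. Fits of only the compared groups gave 1923 for KO_Ctrl vs WT_Ctrl and 1168 for KO_IL4 vs KO_Ctrl, with fewer arrays to estimate the variance.

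Array weights raised the difference of the IL-4 effects to 1548 and that of the culture effects to 3387. The mouse as a random block gave 467 and leaving out wild-type mouse 6 gave 460 for the IL-4 effects. With the spike-in ratio as covariate KO_IL4 vs WT_IL4 gave 1729 and the culture difference 864. With the background ratio as covariate culture gave 4614 genes in wild-type and 5477 in knockout cells. The mouse or its number as a fixed block changed no count by more than 1.5 times (353 for the IL-4 effects). For these moved counts the cause was not tested.

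Leaving out 1 array at a time gave 2506 to 3772 genes for KO_Ctrl vs WT_Ctrl, 2594 to 4149 for KO_IL4 vs WT_IL4 (lowest without KO_IL4 9), 4713 to 5504 for WT_IL4 vs WT_Ctrl, 1211 to 1964 for KO_IL4 vs KO_Ctrl (lowest without KO_IL4 7), and 97 to 1309 for the difference of the IL-4 effects (without KO_IL4 9 and KO_Ctrl 8). It gave 7383 to 9452 and 10003 to 11565 for culture in wild-type and knockout cells, and 1083 to 1966 for their difference.

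Among results called with or without the alternative, the direction of the test reversed with the background ratio as covariate or quantile normalization, and the cause was not tested. Small medians of lists called in neither changed sign under other alternatives too, such as neutrophil markers in KO_Ctrl vs KO_Pre with median centring (0.00845) and marginal zone markers in KO_IL4 vs WT_IL4 without wild-type mouse 6 (0.00536). In KO_Ctrl vs KO_Pre the covariate reversed the direction of the list test for T cell and neutrophil markers, whose medians of -0.98 and -1.99 kept their sign (-0.28 and -0.09 without it), and gave Dock1 0.13, Tcf7l1 0.0325 and Rps19 -0.078. In WT_Ctrl vs WT_Pre it gave Pik3ap1 0.0599 and Rrp12 0.087. Quantile normalization gave -0.0178 for Msmo1, KO_IL4 vs WT_IL4. An estimated correlation ended all 11 list calls for KO_Ctrl vs WT_Ctrl, all 8 for KO_IL4 vs WT_IL4 and 12 for KO_Pre vs WT_Pre. It ended 12, 10, 10, 15, 17 and 14 in the other comparisons. Quantile normalization ended 5 list calls in KO_IL4 vs WT_IL4 and 2 in WT_IL4 vs WT_Ctrl, named above. It ended 4 in KO_IL4 vs KO_Ctrl (marginal zone, plasma cell, monocyte, oxidative phosphorylation) and 2 for the IL-4 difference (MHC class II, cholesterol biosynthesis). It ended 6 in KO_Ctrl vs KO_Pre (B1, heat shock and ribosome lists among them) and 4 in KO_Pre vs WT_Pre. It ended 2 each in WT_Ctrl vs WT_Pre and the culture difference. The background ratio as covariate ended 4 each in WT_Ctrl vs WT_Pre and the culture difference and 2 in KO_Pre vs WT_Pre. It ended 3 in KO_Ctrl vs KO_Pre (B1 markers among them) and 1 each in some others (neutrophil markers in WT_IL4 vs WT_Ctrl). Without wild-type mouse 6 the NK cell list was no longer called in KO_Ctrl vs WT_Ctrl, WT_IL4 vs WT_Ctrl and the difference of the IL-4 effects. A filter for missing values was not run, as there are none. Signal over background was not analysed here, so its effect on dim probes is open.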

Other observations

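Markers of germinal centre and memory B cells did not pass as a group in any of the 9 comparisons, and neither did stromal and endothelial markers or NF-kB targets after culture. With IL-4 the 10 germinal centre and memory markers had a median of 0.34 in wild-type cells (2 higher and 3 lower, adjusted p = 0.989). The 20 NF-kB targets, which answer to inflammatory and receptor signals, had 5 higher and 6 lower genes in KO_Ctrl against WT_Ctrl (adjusted p = 0.554). Genes of glycolysis and glucose uptake had 4 higher and 3 lower of 19 with IL-4 in wild-type cells (adjusted p = 0.608). Those of oxidative phosphorylation were higher with IL-4 in knockout cells (2 of 23, median 0.11, adjusted p = 0.00641; adjusted p = 0.265 with an estimated correlation).

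Heat shock genes, which encode chaperones, fell with culture in knockout cells (9 of 13 lower and 1 higher, adjusted p = 0.0154; adjusted p = 0.364 with an estimated correlation). Transitional B cell markers fell with IL-4 in knockout cells (3 of 11 lower, median -0.40, adjusted p = 0.00701; adjusted p = 0.274 with an estimated correlation). Cytosolic ribosomal protein genes were not called between the genotypes without IL-4 (27 genes, adjusted p = 0.998). Before culture, NF-kB targets were lower in the knockout as a group (median -0.13, adjusted p = 0.000422; adjusted p = 0.111 with an estimated correlation) with 0 of 20 genes called by limma.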
